A study of Rattus norvegicus with 9 samples.

How the data were processed

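The data are 9 single-colour expression arrays of rat cortical neuron cultures, 3 in each of 3 groups: neurons in tetrodotoxin (TTX) for 48 h, and neurons collected 15 min (W15) or 45 min (W45) after the toxin was removed. Per the labels' protocols, the neurons were dissociated from cortices of prenatal pups, grown in Neurobasal medium with B27 or NS21, and used at 11 to 15 days in culture. RNA was isolated on columns with DNase digestion, and Cy3-labelled cRNA was made from 500 ng of total RNA. Per the file headers, the arrays were Agilent rat arrays of design 014879, read with Feature Extraction 9.5.3.1 (9.5 per the submitters' processing notes) and protocol GE1-v5_95_Feb07, and probe positions refer to the rn3 build.

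Per the file headers, the values of each scanner file are spot intensities of the Cy3 channel, and the processed signal is the intensity after background subtraction and detrending within the array, with no scaling between arrays. The deposited value table of the series holds the same intensity values, since its largest difference from the processed signal was 0. It was therefore run as the alternative without scaling between arrays.

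Each array had 45018 spots, of which 1639 control spots were left out because they measure no rat gene, and 43379 probe spots for 41012 probes; 263 probes are printed in 10 spots each, and these were averaged. Spots that the scanner software marked as outliers were set to missing, 49 to 111 per array, and a probe with more than 1 missing array was left out. The log2 processed signal minus the array's 75th percentile was the value analysed. A probe was kept when it stood well above background on all 3 arrays of at least 1 group, which 30323 probes did. Probes were named by matching accession (10735 probes), symbol (5571), other accession (83) or synonym (3705) to the RefSeq gene table of the GRCr8 assembly, used only for names and for gene order, and 20918 probes kept the name in the files. In all, 20205 probes carried a gene symbol. Each gene was represented by its brightest kept probe (3670 genes had several), which gave 25787 genes or features, 12359 of them with a symbol. The depth of an array is its signal over background: 72.4 to 77.9% of probes stood well above background. Correlations of arrays within a group lay between 0.984 and 0.996, and the SD of the log2 difference between arrays of a group between 0.313 and 0.604.

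All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a mean per group and no covariate. Each of the 3 comparisons was a two-sided moderated test with empirical Bayes shrinkage of the variance, with 6 residual degrees of freedom and a median of 9.2 after shrinkage. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called higher or lower. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so none was used for single genes. Where a gene was not above background on any array of 1 group, its fold is given as at least the fold over the mean background limit of those arrays. A set of 33 gene lists was tested with limma's camera (preset correlation 0.01, at least 5 measured members, adjusted over all lists and comparisons together), with fry and with a correlation estimated for each list as alternatives. The lists cover immediate early, late-response and feedback genes, inflammation, mRNA decay, polymerase pausing and subunits, channels, receptors, synapses, clock, stress, metabolism, ribosome and reference genes, and markers of 9 cell types. The list counts adjusted over the list alone use the same limma p values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

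The lists, the test, the alternatives and the rule for naming genes were chosen before the data were examined, except for the alternatives that use only the 4 arrays of slide 3 or leave out W45 replicates 2 and 3 together. By that rule the text names, against TTX, the 12 genes with a symbol with the largest rise and the 8 with the largest fall among those called whose arrays do not overlap (6 and 6 for 45 against 15 min). It always names Arc, Fos, Egr1, Npas4, Junb, Nr4a1, Ier2, Dusp1, Bdnf and Homer1, and up to 4 members of each list with the largest change. Other features are named only where the text says that they were chosen after their values were seen.

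Slides were read from the array barcodes. Slide 1 held TTX replicate 1, W15 replicate 3 and W45 replicate 1, slide 2 held TTX replicates 2 and 3, and slide 3 held W15 replicates 1 and 2 and W45 replicates 2 and 3. The groups at 15 and 45 min are thus balanced over slides, whereas both comparisons with TTX are partly confounded with slide, and slide 1 alone offers 1 array per group. With slide as a fixed block, the folds against TTX rest on TTX replicate 1 as the only TTX array. Whether replicate numbers pair the samples was checked by correlating each array's deviations from its group mean across genes. Arrays with the same number had a median correlation of 0.225 (0.063 to 0.389) and arrays with another number -0.077, against 0.021 for arrays on the same slide. The numbers thus go with a shared component in the comparisons with TTX. The fit with a replicate block, an alternative fixed in advance, called 5, 41 and 24 genes higher in the 3 comparisons where the unblocked fit called 6, 47 and 31.

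The pipeline was tested on simulated data in which 50 genes per size were changed by 0.5, 1, 2 or 4 on the log2 scale. Of the genes changed by 2, it recovered 100, 94 and 98% in the 3 comparisons, of those changed by 1 it recovered 52, 54 and 64%, and of those changed by 0.5 it recovered 0, 0 and 4%. False calls made up 5.3, 4.7 and 2.9% of calls, and the list that was moved was called each time with 0 other lists. The simulated noise was independent between genes and arrays, with the same spread in every group. The simulation therefore cannot show how correlated genes, slides, replicate numbers or a more variable group affect the calls.

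The alternatives were quantile and median scaling, no scaling, normexp background correction with an offset of 50, no filter on dim probes or a filter on all arrays, slide as a fixed or random block, slide 1 alone, the 4 arrays of slide 3 alone, the replicate block, a trended and robust variance, the mean of all probes of a gene, only the groups compared, leaving out each array in turn, leaving out W45 replicates 2 and 3 together, and the alternative list tests. Transcripts without a probe, isoforms and the pausing of polymerase itself are not measured by these arrays and were not analysed here.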

Results

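Messenger RNA of rat cortical neurons was measured on 9 single-colour arrays, 3 per group. The neurons came from the cortices of prenatal pups, were used at 11 to 15 days in culture. They were kept for 48 h in tetrodotoxin (TTX), a toxin that blocks voltage-gated sodium channels and so stops action potentials. The TTX group was collected in the toxin. The other groups were collected 15 min or 45 min after the toxin had been removed with 3 washes, so that firing could resume. Signals stood well above background for 72.4 to 77.9% of the 41012 probes of each array, and the 75th percentile of the signal lay between 1563 and 2526 on every array. Of the 25787 genes or features tested, 12359 carried a gene symbol. The number of arrays limits the precision. The labels do not say whether replicates are separate cultures, so the p value of a single gene measures only the spread between these samples. Camera's p value for a list sets the list's genes against all other genes at a preset correlation. It therefore does not measure how well a shift repeats between samples. The median log2 fold change of all genes was 0.056 at 15 min and 0.051 at 45 min against TTX. Changes are given relative to the scaling of each array by its 75th percentile. That median moved to 0.208 and 0.129 with a model-based (normexp) background correction and to -0.151 and -0.213 without scaling between arrays.

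The comparison of 15 min after washout with TTX asks which neuronal genes answer fastest once activity returns. It found 6 genes higher, all of them known immediate early or stress-response genes. Npas4, a transcription factor largely specific to neurons and driven by calcium entry, rose by 5.71 ± 0.40 on the log2 scale (SE, n = 3 arrays per group). Fos, the AP-1 transcription factor used as a marker of active neurons, rose 29.3-fold, by 4.87 ± 0.34 on the log2 scale. Junb, which pairs with Fos in AP-1, rose 9.43-fold. The zinc-finger transcription factors Egr1 and Egr4 rose 4.32-fold and 4.25-fold, and Gadd45g, a growth-arrest and DNA-damage-inducible gene, rose 2.43-fold. Limma's adjusted p was 0.00176 for Npas4 and for Fos, 0.00736 for Junb, 0.00681 for Egr1 and for Egr4, and 0.0106 for Gadd45g. For each of the 6 genes all 3 arrays at 15 min lay above all 3 TTX arrays. Of all genes tested, 14% had arrays that did not overlap between these groups, against 10% by chance. Npas4 was not above background on any of the 3 TTX arrays, so its rise is given as at least 19.8-fold over the background limit of those arrays. Its log2 signal relative to the array's 75th percentile was -8.52 ± 0.14 (SD, n = 3) in TTX and -2.82 ± 0.96 at 15 min. The log2 signal of Fos went from -2.84 ± 0.28 to 2.03 ± 0.61 (SD, n = 3), and that of Egr1 from 0.76 ± 0.29 to 2.87 ± 0.22. No gene was called lower by limma. At an unadjusted p under 0.05, 237 genes were lower and 665 were higher. If none changed, a share of 0.05 of the 25787 genes tested would pass, which is more than these counts together.

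The files place the probe of Npas4 (NM_153626) on chromosome 1 at 207752362 to 207752421 in the rn3 build. That of Fos (NM_022197) lies on chromosome 6 at 109564555 to 109564614, and that of Junb (NM_021836) on chromosome 19 at 24837607 to 24837666. The probe of Egr1 (NM_012551) lies on chromosome 18 at 27373819 to 27373878, that of Egr4 (NM_019137) on chromosome 4 at 120009770 to 120009829, and that of Gadd45g (XM_237999) on chromosome 17 at 19231059 to 19231118. Arc (NM_019361), whose protein acts at synapses and in the trafficking of glutamate receptors, has its probe on chromosome 7 at 112806255 to 112806314, and Nr4a1 (NM_024388), an orphan nuclear receptor, on chromosome 7 at 140096879 to 140096938.

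Arc was not called at 15 min. Its log2 fold change was 1.69 ± 0.25 (SE, n = 3 per group, adjusted p = 0.187), with all 3 arrays at 15 min above all 3 TTX arrays. It passed the threshold in 1 of the 22 alternatives that tested it, at an adjusted p of 0.0497 with a trended and robust spread. Ier2, an immediate early transcriptional regulator, had a log2 fold change of 1.01 ± 0.16 (adjusted p = 0.261), with an adjusted p of 0.0497 under the same alternative. Nr4a1 had 0.45 (adjusted p = 0.991), Dusp1, a phosphatase that switches off MAP kinases, 0.37, Bdnf, the neurotrophin, -0.14, and Homer1, a postsynaptic scaffold, 0.00 ± 0.12.

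**Figure D1:**
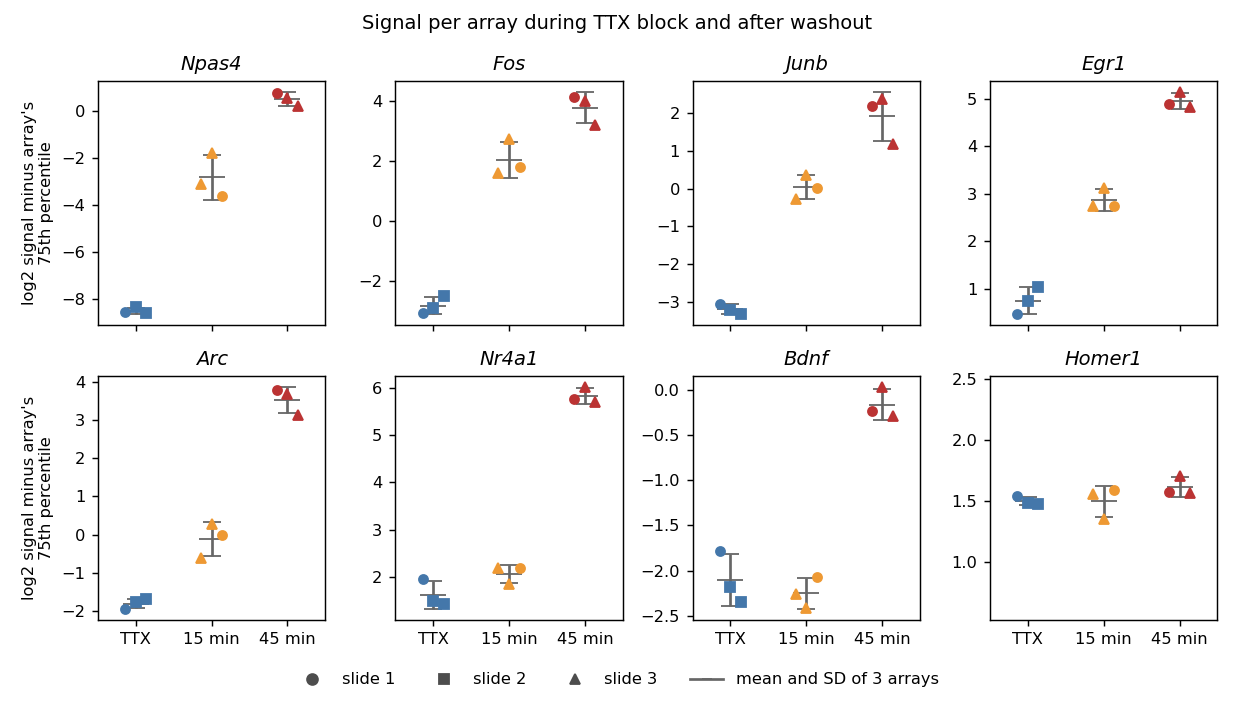
Signal of 8 genes on each of the 9 arrays (vertical axis, log2 signal minus the array's 75th percentile; horizontal axis, group), with marker shape showing the slide and bars the mean and SD of 3 arrays. Npas4, Fos, Junb and Egr1 were higher than in TTX at both times, the mean of Nr4a1 went from 1.63 in TTX to 2.08 and 5.83, and that of Homer1 from 1.5 to 1.5 and 1.61.

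Of the 33 gene lists fixed in advance, 3 were shifted at 15 min by limma's camera test. Among the immediate early transcription factors, 5 of 26 measured members rose (Npas4, Fos, Junb, Egr1 and Egr4), 8 when adjusted over the list alone. The median log2 fold change was 0.27 (adjusted p = 4.11e-17, and adjusted p = 0.0133 with an estimated correlation). Among the immediate early effectors, the genes whose products act outside transcription, 1 of 19 rose (Gadd45g), 4 when adjusted over the list alone. The median of this list was 0.16 (adjusted p = 0.0154, and adjusted p = 0.128 with an estimated correlation). The largest change of this list was that of Arc, which was not called, and after Gadd45g came Ccn1 (a secreted matrix protein, 0.88) and Gadd45b (0.83), also not called. Among the late-response activity genes, 0 of 20 passed limma's test, also when adjusted over the list alone. The median was -0.10 (adjusted p = 0.0434, and adjusted p = 0.557 with an estimated correlation). Inhba, a subunit of activin, had 0.45, and the neuropeptide genes Crh and Pdyn had -0.35 and -0.27. Lists of ERK feedback genes (median 0.07, adjusted p = 0.686) and of cAMP and CREB feedback genes (median 0.16, adjusted p = 0.909) were not shifted. The median of the effectors was -0.05 without scaling between arrays, and that of the late-response genes was 0.04 with the normexp correction. Both kept the side of the median of all genes that they had before.

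The arrays lay on 3 slides that the groups did not fill evenly. TTX replicates 2 and 3 were alone on their slide. The blocked folds against TTX and the slide 1 values therefore both rest on TTX replicate 1, and are not separate checks. With slide as a fixed block 0 of the 6 genes passed limma's adjusted threshold, although all 6 kept their sign and an unadjusted p under 0.05. The median log2 fold change of the 6 was 2.67 without the block and 2.75 with it, while the median SE went from 0.24 to 0.39. Npas4 had at least 4.17 with the block (5.51 as computed, adjusted p = 0.15), Fos 5.16 (adjusted p = 0.147) and Arc 2 (adjusted p = 0.98). On slide 1, with 1 array per group, the difference was at least 3.63 for Npas4 (4.97 as computed), 4.86 for Fos, 3.08 for Junb, 2.26 for Egr1, 2.03 for Egr4, 1.26 for Gadd45g and 1.92 for Arc. The transcription factor list had a median of 0.49 with the block (adjusted p = 1.71e-13) and 0.50 on slide 1, whereas the effectors had 0.12 (adjusted p = 0.407) and 0.05, and the late-response genes -0.14 (adjusted p = 0.407) and 0.04. The normexp correction left 2 genes called, Fos and Egr1, and ended the calls of Npas4 (2.55, adjusted p = 0.194), Junb (2.96, 0.0676), Egr4 (1.80, 0.124) and Gadd45g (1.32, 0.277). Without scaling between arrays the call of Gadd45g was also lost (1.08, 0.536), and with the replicate number as a block it reached 0.0649. Lists not shifted in the main fit that were shifted with the slide block were those of GABA receptors and synthesis (median -0.30, adjusted p = 0.00154), microglia and macrophage markers (0.37, adjusted p = 0.031) and glycolysis and hypoxia genes (0.22, adjusted p = 0.0401). With normexp the last of these was shifted the other way relative to all genes (adjusted p = 0.00218).

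Leaving out 1 array changed the number of genes higher at 15 min from 6 to 4 without TTX replicate 1, 2 without TTX replicate 2, 3 without TTX replicate 3, 2 without W15 replicate 2, 3 without W15 replicate 3 and 8 without W45 replicate 3. W15 and W45 stand for the groups 15 and 45 min after washout. The calls of Npas4 and Fos held in all 9 fits that leave out 1 array. Egr1 reached an adjusted p of 0.056 without TTX replicate 2 and 0.058 without W15 replicate 2. Egr4 reached 0.056 and 0.0804 without TTX replicates 2 and 3 and 0.0603 and 0.0565 without W15 replicates 2 and 3. Junb reached 0.0547, 0.0563 and 0.0842 without TTX replicates 1, 2 and 3, and 0.0603 and 0.0576 without W15 replicates 2 and 3. Gadd45g reached 0.0989, 0.109, 0.126, 0.0603 and 0.0747 without the same 5 arrays. The count of genes lower became 1 without TTX replicate 2 and 2 without W15 replicate 3. The call of the late-response genes was lost without TTX replicate 1 (adjusted p = 0.0985), TTX replicate 3 (0.157), W15 replicate 1 (0.635), W45 replicate 1 (0.0605) or W45 replicate 3 (0.0537). It was also lost with quantile scaling (0.156), the mean of all probes (0.236), probes above background on all arrays (0.0917), no scaling (0.116), only the groups compared (0.0779) and fry (0.674). That of the effectors was lost without W45 replicate 1 (0.0577), with normexp (0.19) and with only the groups compared (0.131). The list of GABA receptors and synthesis, with an adjusted p of 0.0742 on all arrays, reached 0.0365 without TTX replicate 2, 0.0456 without W15 replicate 2 and 0.0337 without W45 replicate 1. It also reached 0.00143 with normexp, 0.0224 without scaling, 0.039 without the filter on dim probes and 0.0453 with only the groups compared. Without both W45 replicates 2 and 3, an alternative chosen after the data were seen, the calls of the effectors (0.0943) and of the late-response genes (0.0675) at 15 min were lost and the GABA list reached 0.0418.

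The comparison of 45 min after washout with TTX asks how far the response had spread by then. It found 47 genes higher and 5 lower, and 37 of the genes that rose carried a symbol. Npas4 rose by at least 201-fold over the background limit of the TTX arrays, on none of which it stood above background. As computed from the signals, its log2 rise was 9.05 ± 0.40 (SE, n = 3 arrays per group). With the normexp correction its rise was 5.44 and still called. Fos rose 97.6-fold (6.61 ± 0.34), Arc rose 40-fold (5.32 ± 0.25), Egr4 rose 39.5-fold (5.30 ± 0.18) and Junb rose 34.5-fold (5.11 ± 0.30). Ccn1 rose 19.7-fold, Egr2 18.9-fold, Nr4a1 18.4-fold and Egr1 18.3-fold. Ch25h, the enzyme that makes 25-hydroxycholesterol, rose 10-fold. Edn1, the precursor of the vasoactive peptide endothelin-1, rose 8.65-fold, and Fosl1, an AP-1 partner related to Fos, rose 7.21-fold. Limma's adjusted p was 6.54e-06 for Egr4, 8.30e-06 for Egr2, 9.40e-06 for Npas4, Egr1, Nr4a1 and Ch25h, 1.07e-05 for Arc, 1.97e-05 for Edn1, 2.12e-05 for Fos, 3.53e-05 for Ccn1, 5.15e-05 for Junb and 0.0111 for Fosl1. For all 52 genes called, the 3 arrays at 45 min and the 3 TTX arrays did not overlap, as was so for 11.7% of all genes tested against 10% by chance. Edn1 stood above background on 1 of the 3 TTX arrays only, and with the normexp correction its log2 rise was 1.23 and not called (limma adjusted p = 0.945). That correction adds an offset of 50 to every signal, which by itself lowers folds near background.

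Among the other genes fixed for naming, Ier2 rose by 2.28 on the log2 scale (adjusted p = 1.86e-04), Dusp1 by 2.69 (adjusted p = 4.94e-05) and Bdnf by 1.94 ± 0.18 (SE, adjusted p = 0.00185). A second Bdnf probe had a log2 fold change of 2.41. Homer1 had a log2 fold change of 0.11 ± 0.12 (adjusted p = 0.916). Its probe has no coordinates on the array, so which transcripts of the gene it reads was not settled. The log2 signal of Arc went from -1.80 ± 0.12 to 3.52 ± 0.35 (SD, n = 3), that of Nr4a1 from 1.63 ± 0.30 to 5.83 ± 0.17, and that of Bdnf from -2.10 ± 0.29 to -0.16 ± 0.17. No gene with a symbol was called lower. The 5 features called lower carry an expressed-sequence cluster number in place of a symbol, and they are named here after their values were seen. The array annotation describes TC527037 as partly similar to human sepiapterin reductase and the others as unknown. TC533180 fell by 1.42 on the log2 scale, TC543456 fell by 1.34, TC527037 fell by 1.33, TC532529 fell by 1.13 and TC568008 fell by 0.99. With the replicate number as a block 6 features were lower, of which 3 were among these 5. With slide as a fixed block or with the normexp correction, none of these 5 was called lower. At an unadjusted p under 0.05, 972 genes were higher and 689 were lower, where a share of 0.05 of the 25787 genes tested would pass if none changed.

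The shift at 45 min covered 5 of the 33 lists. Of the 26 immediate early transcription factors, 15 rose, 23 when adjusted over the list alone, led by Npas4, Fos, Egr4 and Junb. The median log2 fold change was 1.71 (adjusted p = 1.56e-61, and adjusted p = 0.00116 with an estimated correlation). Of the 19 effectors, 6 rose, 13 when adjusted over the list alone, led by Arc, Ccn1, Gadd45g (2.76) and Dusp1. Their median was 0.77 (adjusted p = 2.88e-23, and adjusted p = 0.00116 with an estimated correlation). Of the 13 genes that feed back on the ERK pathway, 3 rose, 8 when adjusted over the list alone: Dusp1, Dusp6 (1.77 ± 0.23, adjusted p = 0.018) and Dusp5 (1.61 ± 0.13, adjusted p = 7.42e-04), all phosphatases of MAP kinases. The median of that list was 0.54 (adjusted p = 1.32e-10, and adjusted p = 0.00576 with an estimated correlation). Dusp4 had 1.13 (adjusted p = 0.181). Of the 11 genes of cAMP and CREB feedback, 2 rose, Nr4a1 and its relative Nr4a2 (1.79 ± 0.20, adjusted p = 0.0078), 8 when adjusted over the list alone. The median was 0.70 (adjusted p = 7.83e-10, and adjusted p = 0.00602 with an estimated correlation). In the same list Rgs2, a brake on G-protein signalling, had 1.26 (adjusted p = 0.399) and the salt-inducible kinase Sik1 had 0.91 (adjusted p = 0.709). Of the 20 late-response genes, 3 rose, 5 when adjusted over the list alone: Bdnf, the secreted neuropeptide precursor Vgf (1.31 ± 0.16, adjusted p = 0.0111) and Rgs4, another regulator of G-protein signalling (1.02 ± 0.13, adjusted p = 0.0192). The median of the late-response genes was 0.26 (adjusted p = 7.10e-07, and adjusted p = 0.0632 with an estimated correlation). It was 0.00 without scaling between arrays, where the median of all genes was -0.213. The neuropeptide gene Crh had 0.98 (adjusted p = 0.144). The lists share members, so they are not 5 separate results. Of the 11 cAMP and CREB genes, 7 (Crem, Nr4a1, Nr4a2, Nr4a3, Per1, Rgs2 and Sik1) are also among the transcription factors or effectors, and so were 7 of the 8 that rose when adjusted over the list alone. The 4 others had a median of 0.13. Dusp1 is in the effector list and in the ERK list, and the late-response list shares 0 genes with the others.

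**Figure D2:**
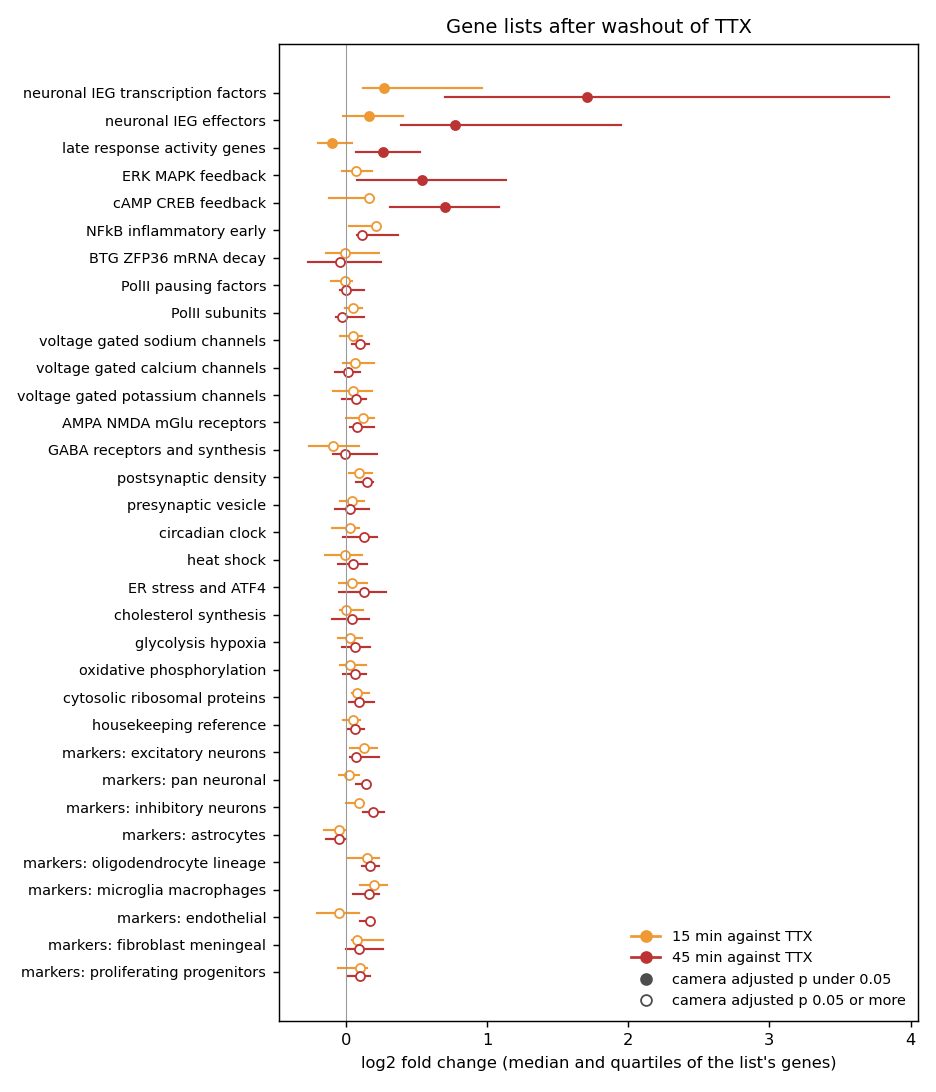
Median log2 fold change against TTX of the 33 gene lists (horizontal axis), with lines spanning the quartiles of the list's genes, at 15 min and at 45 min; filled points have a camera adjusted p under 0.05. At 45 min the medians of the 5 shifted lists lay between 0.26 and 1.71, and those of the 28 other lists between -0.05 and 0.19.

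With slide as a fixed block, 19 of the 52 genes were still called at 45 min, and all 52 kept their sign and an unadjusted p under 0.05. The median log2 fold change of the 52 in their called direction was 1.80 without the block and 1.90 with it, and the median on slide 1 was 1.86. The median SE went from 0.18 to 0.28. Blocked values were at least 7.51 for Npas4 (8.85 as computed, adjusted p = 0.0068), 6.90 for Fos (0.00996), 5.63 for Arc (0.00595), 5.43 for Egr4 (0.0014) and 3.89 for Nr4a1 (0.00469). On slide 1 alone these genes differed by at least 8.05 (9.39 as computed), 7.2, 5.71, 5.60 and 3.80. The block ended the calls of Bdnf (1.67, adjusted p = 0.183), Fosl1 (3.61, 0.0886), Dusp5 (1.54, 0.145), Dusp6 (2.08, 0.407), Vgf (1.24, 0.505) and Rgs4 (0.99, 1). The list medians with the block and on slide 1 were 1.73 and 1.80 for the transcription factors (adjusted p = 7.59e-61), and 0.51 and 0.41 for the effectors (1.36e-16). They were 0.45 and 0.40 for ERK feedback (3.38e-07), 0.36 and 0.23 for cAMP and CREB feedback (4.72e-06), and 0.37 and 0.18 for the late-response genes (1.13e-06). Glycolysis and hypoxia genes (0.35, adjusted p = 0.00532) and postsynaptic density genes (0.21, adjusted p = 0.0401) were shifted only with the block.

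The number of genes higher at 45 min changed from 47 to 28, 27 and 31 without TTX replicates 1, 2 and 3, to 80 without W45 replicate 1 and to 30 without W45 replicate 2. The number lower changed from 5 to 1, 3 and 1 without TTX replicates 1, 2 and 3, to 2, 1 and 2 without W15 replicates 1, 2 and 3, and to 94, 1 and 29 without W45 replicates 1, 2 and 3. Single calls were lost for Fosl1 without TTX replicate 2 (adjusted p = 0.0583) or W45 replicate 2 (0.0745), for Nr4a2 without TTX replicate 1 (0.0598) or 2 (0.0544). That of Vgf was lost without TTX replicate 2 (0.0544) or 3 (0.0594). The call of Dusp6 was lost without TTX replicate 1 (0.124) or 2 (0.11) and without W45 replicate 2 (0.0745) or 3 (0.055). Rgs4 lost its call without TTX replicate 1 (0.105), 2 (0.121) or 3 (0.153) and without W45 replicate 2 (0.0956). Calls were gained for Dusp4 (0.0143) and Sik1 (0.0371) without W45 replicate 1 and for Rgs2 (0.00378) without W45 replicate 3. The normexp correction ended the calls of Ch25h (2.44, adjusted p = 0.0599), Fosl1 (2.07, 0.0771), Edn1 (1.23, 0.945), Nr4a2 (1.45, 0.196), Dusp6 (1.87, 0.0891), Vgf (1.26, 0.139) and Rgs4 (1.18, 0.218). Without scaling between arrays the calls of Nr4a2 (1.52, adjusted p = 0.0922), Dusp6 (1.51, 0.134), Vgf (1.04, 0.25) and Rgs4 (0.76, 0.386) were lost. Dusp6 and Rgs4 reached 0.0621 without the filter on dim probes, Vgf and Rgs4 reached 0.0701 and 0.0716 with only the groups compared, and Rgs4 reached 0.0648 with the replicate block, which kept 42 of the 52 calls.

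The SD of the log2 difference between arrays was 0.516 to 0.604 within W45 and 0.313 to 0.371 within TTX, while the fit shares 1 spread over the groups. W45 replicates 2 and 3 stood apart from the other arrays and from each other. They lay at 34 and 51.8 on the first principal component, which held 24.3% of the variance. All other arrays lay between -27.5 and -1.9, with W15 replicates 1 and 2, on the same slide, at -9.8 and -5.4. On the second component, which held 22.1% of the variance, W45 replicates 2 and 3 lay at opposite ends, at 43.3 and -33.8. Without both arrays, in a fit that assumes the lone W45 array to vary like the other groups, 33 genes were higher at 45 min than in TTX, 25 of them among the 47. The genes lower became 45, of which 1 was among the 5. Between the times 17 were higher, 13 of them among the 31 called on all arrays, and 16 lower, of which 0 were among the 3. Of the genes named at 45 min against TTX, the calls of Fosl1 (2.87, adjusted p = 0.122), Dusp6 (1.77, 0.143), Vgf (1.38, 0.0836) and Rgs4 (0.90, 0.143) were lost and that of Rgs2 (1.72, 0.0268) was gained. Between the times those of Bdnf (2.01, adjusted p = 0.0512), Egr1 (2.01, 0.0547), Npas4 (3.63, 0.0945), Gadd45b (2.15, 0.0519), Nr4a2 (1.82, 0.062), Vgf (1.52, 0.0661), Crh (1.49, 0.111) and Rgs4 (0.87, 0.154) were lost and that of Junb (2.13, 0.0485) was gained. The 5 lists stayed shifted in both comparisons, with medians against TTX of 1.51 for the transcription factors, 0.42 for the effectors, 0.39 for ERK feedback, 0.49 for cAMP and CREB feedback and 0.08 for the late-response genes. Cytosolic ribosomal proteins (0.15, adjusted p = 0.00469) were then shifted against TTX, and microglia and macrophage markers (-0.26, 0.0479) between the times.

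The comparison of 45 with 15 min after washout tests directly how the response changed between the 2 times. Its groups were spread evenly over the slides. Of the genes tested, 31 were higher and 3 lower at 45 min. Nr4a1 was 13.5-fold higher at 45 min (3.75 ± 0.18 on the log2 scale, SE, n = 3 per group), Arc 12.4-fold (3.63 ± 0.25), Ccn1 10.7-fold (3.42 ± 0.23), Npas4 10.2-fold (3.34 ± 0.40) and Egr4 9.31-fold (3.22 ± 0.18). Edn1, not above background on any array at 15 min, was at least 8.17-fold higher than the background limit of those arrays, but with the normexp correction it differed by 0.52 on the log2 scale and was not called (adjusted p = 0.692). Adjusted p was 4.97e-05 for Nr4a1 and Edn1, 3.19e-04 for Arc and Ccn1, 1.20e-04 for Egr4 and 0.0168 for Npas4. All 34 genes called had arrays that did not overlap between the times, as was so for 8.1% of all genes tested against 10% by chance. Dusp1 was higher by 2.33 (adjusted p = 3.13e-04), Egr1 by 2.08 (0.0018), Bdnf by 2.08 (0.00144) and Ier2 by 1.27 (0.0209). Fos (1.74 ± 0.34, adjusted p = 0.192), Junb (1.87 ± 0.30, adjusted p = 0.0743) and Homer1 (0.12 ± 0.12, adjusted p = 0.881) were not called between the times. The 3 features lower at 45 min have no gene symbol and are named after their values were seen. XM_343376 fell by 1.60 on the log2 scale, TC543456 fell by 1.30 and AW142587 fell by 1.24.

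The 5 lists shifted at 45 min against TTX were also shifted between the times, with the same shared members. Of the 26 transcription factors 10 were higher at 45 min, 22 when adjusted over the list alone. Their median was 1.23 (adjusted p = 1.18e-46, and adjusted p = 0.0018 with an estimated correlation). Of the 19 effectors 6 were higher, 12 when adjusted over the list alone (median 0.76, adjusted p = 9.00e-23). Of the 20 late-response genes 4 were higher, 7 when adjusted over the list alone (median 0.25, adjusted p = 6.32e-11). These were Bdnf, Vgf (1.45, adjusted p = 0.00856), Crh (1.33, adjusted p = 0.0349) and Rgs4 (1, adjusted p = 0.0279). Of the 13 ERK feedback genes 2 were higher (Dusp1 and Dusp5, 1.56), 8 when adjusted over the list alone (median 0.46, adjusted p = 2.69e-10). Of the 11 cAMP and CREB feedback genes 2 were higher (Nr4a1 and Nr4a2, 1.49), 7 when adjusted over the list alone (median 0.62, adjusted p = 2.27e-10). All 7 are also among the transcription factors or effectors, and the 4 other cAMP and CREB genes had a median of 0.07. With an estimated correlation the adjusted p was 0.00116 for the effectors, 0.0202 for the late-response genes and 0.00576 for both feedback lists. With slide as a fixed block the adjusted p was 6.3e-43, 7.26e-21, 6.16e-10, 2.79e-09 and 6.16e-10 for the transcription factors, effectors, late-response, ERK and cAMP lists. Their medians were 1.41, 0.50, 0.18, 0.37 and 0.50 on slide 1 and 1.19, 0.75, 0.39, 0.51 and 0.75 on slide 3.

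The block left 22 of the 34 genes called between the times, with a median log2 fold change of 1.76 with and without it, of 1.71 on slide 1 and of 1.81 on slide 3, where all 34 kept their sign. It ended the calls of Npas4 (adjusted p = 0.066), Ier2 (0.0706), Gadd45b (0.125) and Rgs4 (0.147), while their fold changes were the same with it. The number of genes higher changed from 31 to 20 without TTX replicate 2 or 3, to 18 and 19 without W15 replicates 1 and 2, to 63 without W45 replicate 1 and to 18 without W45 replicate 2. The number lower changed from 3 to 1 without TTX replicate 1, to 0 and 1 without W15 replicates 1 and 2, and to 128, 0 and 30 without W45 replicates 1, 2 and 3. The call of Npas4 was lost without TTX replicate 3 (adjusted p = 0.0507), W15 replicate 1 (0.114) or W45 replicate 2 (0.112). Vgf lost its call without W15 replicate 1 (0.0653) or 2 (0.0627). The call of Ier2 was lost without TTX replicate 1 (0.0587), 2 (0.0696) or 3 (0.0652), W15 replicate 1 (0.127), 2 (0.07) or 3 (0.0842), or W45 replicate 2 (0.111). Nr4a2 lost its call without TTX replicate 1 (0.0708), 2 (0.0826) or 3 (0.0823), W15 replicate 1 (0.115) or 2 (0.15), or W45 replicate 2 (0.112). The same held for Crh without TTX replicate 1 (0.0689), 2 (0.0704) or 3 (0.102), W15 replicate 1 (0.199) or 2 (0.171), or W45 replicate 2 (0.18). Rgs4 lost its call without TTX replicate 1 (0.0766), 2 (0.0915) or 3 (0.0844), W15 replicate 1 (0.165) or 2 (0.171), or W45 replicate 2 (0.154) or 3 (0.055). Calls between the times were gained for Junb (0.00592) and Rgs2 (0.00953) without W45 replicate 3. They were gained for Sik1 (0.0127), the clock gene Per1 (0.0381) and Spry1, an inhibitor of ERK signalling (0.0421), without W45 replicate 1, and for Spry1 without W15 replicate 3 (0.0334). With a trended and robust spread Junb (0.0283), Dusp6 (0.0285) and Spry1 (0.0214) were called, and Spry1 also with the mean of all probes (0.0139) and with probes above background on all arrays (0.0458). The normexp correction ended the calls of Crh (0.35, adjusted p = 0.692), Ier2 (1.07, 0.537), Nr4a2 (1.07, 0.628), Rgs4 (1.13, 0.286) and Vgf (1.43, 0.092). Without scaling between arrays Crh (0.202), Ier2 (0.176), Nr4a2 (0.181), Rgs4 (0.292) and Vgf (0.083) lost theirs. Without the filter on dim probes the calls of Npas4 (0.0621), Ier2 (0.074), Gadd45b (0.0957), Nr4a2 (0.0957), Rgs4 (0.0947) and Crh (0.114) were lost. The same 6 genes reached 0.123, 0.173, 0.193, 0.193, 0.24 and 0.173 with only the groups compared. Crh reached 0.0713 with quantile scaling and 0.0569 with slide as a random block.

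All 6 genes called higher at 15 min were also called higher at 45 min, 41 genes were called at 45 min only, and 0 at 15 min only. A gene not called at 15 min is not thereby unchanged, since Arc had a log2 fold change of 1.69 then. The feature AF030090, named after its values were seen, was called at 45 min only, with 3.07 at 15 min and 2.74 at 45 min. If the calls were independent, 0.0109 genes would be called at both times. In 50 simulations of groups without any change against the same TTX arrays the mean and the maximum were 0, a count that the adjusted threshold leaves little room to exceed where nothing changed, so it adds nothing to the calls themselves. Of the 6 genes, 4 (Npas4, Egr1, Egr4 and Gadd45g, the last by 1.47 on the log2 scale with an adjusted p of 0.00144) were also called between the times, as were 30 of the 47 genes higher at 45 min. The fold changes at the 2 times correlated across genes with r = 0.428, against a mean of 0.502 in the simulations (0.475 to 0.516), which share the TTX arrays in the same way. Their covariance was 0.0311, against a simulated mean of 0.0278 (0.0261 to 0.029), a difference of 0.00336. The simulations hold no component shared by replicate number or by slide, so they do not model that part of the real arrays. They also give every group the same spread. In the real arrays the SD of the log2 difference was 0.313 to 0.371 within TTX, 0.407 to 0.416 within W15 and 0.516 to 0.604 within W45. The correlation and covariance expected without change depend on these spreads, so the simulated ranges cannot show whether the observed values are low or high. The 3 TTX arrays were not split between the comparisons, so part of what the 2 comparisons share may come from these arrays. Genes are not independent replicates. With slide as a fixed block 0 genes were called at both times, since none was called at 15 min. The number called at both times was 3 without TTX replicate 2 or 3, 2 without W15 replicate 2 and 3 without W15 replicate 3.

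**Figure D3:**
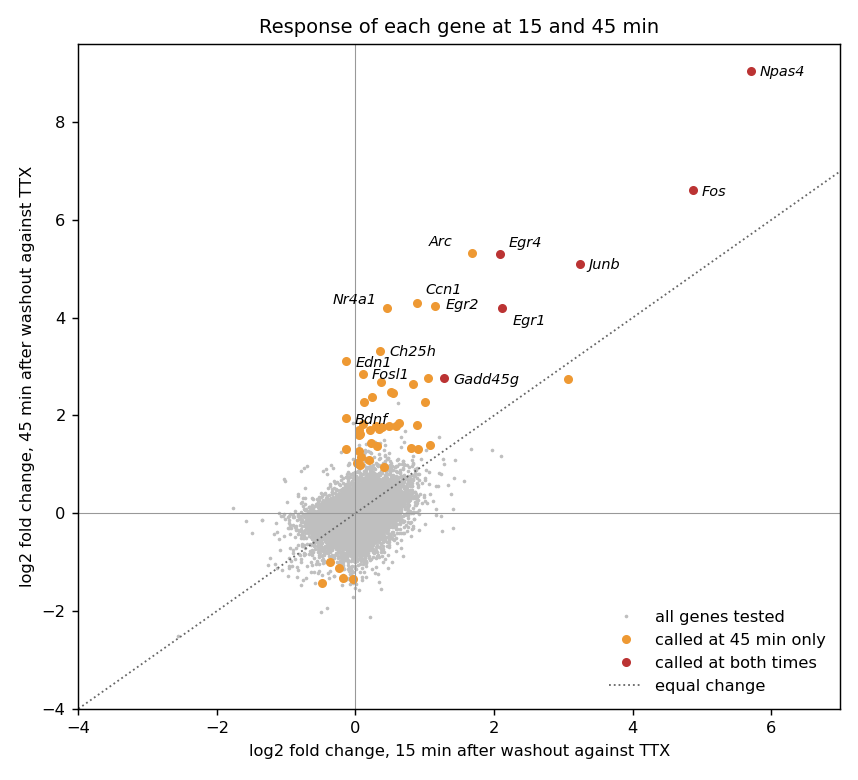
Log2 fold change against TTX of each of the 25787 genes tested, at 15 min (horizontal axis) and at 45 min (vertical axis); red points were called at both times, orange at 45 min alone, and the dotted line marks equal change. The 6 genes called at both times lie above the line, with Npas4 at 5.71 and 9.05 as computed and Gadd45g at 1.28 and 2.76. Npas4 was not above background on any TTX array, so its rises are at least 4.31 and 7.65.

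The other 28 lists were not shifted in any comparison by camera in the main fit. With the normexp correction, 7 of them were shifted upward between the times relative to all genes, with an adjusted p of at most 0.0323. These were cytosolic ribosomal proteins, neurons of all kinds, proliferating progenitors, oxidative phosphorylation, GABA receptors and synthesis, glycolysis and hypoxia, and housekeeping reference genes. All of these but the lists of neurons of all kinds and of reference genes were shifted downward at 15 min with it, also at 0.0323 or below. At 45 min against TTX the early NF-kB and inflammatory genes had a median of 0.11 (adjusted p = 0.108, and 0.0173 without scaling between arrays) with 0 of 8 past limma's test and 2 when adjusted over the list alone. The ER stress and ATF4 genes had a median of 0.13 (adjusted p = 0.211), with 1 of 15 higher. This was the phosphatase subunit Ppp1r15a (1.37, adjusted p = 0.00766), which was not among the genes run under the alternatives. By limma's fry, which asks whether a list's genes move on balance one way, the adjusted p was 0.0143 for each of these lists. In the list of BTG, ZFP36 and mRNA decay genes, 1 of 13 rose (Btg2, an antiproliferative immediate early gene, 2.39), with a median of -0.04 (adjusted p = 0.9). The genes that control pausing of RNA polymerase II had a median of 0.00 (adjusted p = 0.958) with 0 of 14 past the test. The polymerase subunits had a median of -0.03 (adjusted p = 0.788) with 0 of 9. Voltage-gated sodium channels, the family that TTX targets, had a median of 0.10 (adjusted p = 0.846), calcium channels 0.01 (0.948) and potassium channels 0.07 (0.958). Glutamate receptors had a median of 0.08 (adjusted p = 0.62), GABA receptors and synthesis -0.01 (0.948), postsynaptic density genes 0.15 (0.211) and presynaptic vesicle genes 0.03 (0.847). Medians were 0.13 for circadian clock genes (adjusted p = 0.393), 0.05 for heat shock genes (0.948), and 0.04 for cholesterol synthesis (0.948). They were 0.06 for glycolysis and hypoxia (0.909), 0.06 for oxidative phosphorylation (0.87), 0.09 for cytosolic ribosomal proteins (0.193) and 0.06 for housekeeping reference genes (0.712). The median, the mean or the direction of the test differed in sign for the lists of mRNA decay, calcium channel, potassium channel, GABA, presynaptic vesicle and heat shock genes.

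Markers of cell types were likewise not shifted at 45 min in the main fit. Medians were 0.07 for excitatory neurons (adjusted p = 0.723), 0.14 for neurons of all kinds (0.225), 0.19 for inhibitory neurons (0.172), and -0.05 for astrocytes (0.757). They were 0.17 for the oligodendrocyte lineage (0.363), 0.16 for microglia and macrophages (0.846), 0.17 for endothelial cells (0.573), 0.09 for fibroblasts of the meninges (0.712) and 0.10 for proliferating progenitors (0.703). Without W45 replicate 2 the oligodendrocyte list reached an adjusted p of 0.0165. Without W45 replicate 3 the cytosolic ribosomal proteins, at 0.193 on all arrays, reached 0.0152. At 15 min the medians of the lists that were not shifted lay between -0.09 (GABA receptors and synthesis, adjusted p = 0.0742) and 0.21 (early NF-kB genes, adjusted p = 0.363). Between the times they lay between -0.12 (microglia and macrophages, adjusted p = 0.554) and 0.21 (endothelial cells, adjusted p = 0.225).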

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

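The fit without both W45 replicates 2 and 3 was chosen after the data were seen, and every other test in this part was chosen before. What singled out the results here is that the response to washout differed between 15 and 45 min by the direct test of 45 against 15 min, with an adjusted p under 0.05. This held for 21 of the named genes that were run under the alternatives in any comparison and for 5 gene lists, which share members. Each of these was higher at 45 min. Not counted are Ppp1r15a and Klf4, also called higher between the times, and the 3 features without a symbol that were called lower.

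Among transcription factors, the log2 difference between the times was 3.75 for Nr4a1, 3.34 for Npas4, 3.22 for Egr4, 3.1 for Egr2, 2.74 for Fosl1, 2.08 for Egr1, 1.49 for Nr4a2 and 1.27 for Ier2. It was 2.15 for Btg2, an antiproliferative gene. Among genes acting at synapses, in the matrix or in signalling, it was 3.63 for Arc, 3.42 for Ccn1, 2.98 for Ch25h, 2.33 for Dusp1, 1.81 for Gadd45b, 1.56 for Dusp5, 1.47 for Gadd45g and 1 for Rgs4. For genes of secreted peptides it was at least 3.03 for Edn1, which was not above background on any array at 15 min (3.25 as computed), 2.08 for Bdnf, 1.45 for Vgf and 1.33 for Crh, but with the normexp correction it was 0.52 for Edn1 and 0.35 for Crh, neither of them called (adjusted p = 0.692 for both). The median of the lists was 1.23 for immediate early transcription factors, 0.76 for immediate early effectors, 0.62 for cAMP and CREB feedback, 0.46 for ERK feedback and 0.25 for late-response genes. The 4 cAMP and CREB genes found in none of the other lists had a median of 0.07. Leaving out 1 array ended the call of Npas4, Ier2, Nr4a2, Rgs4, Vgf or Crh, at an adjusted p from 0.0507 (Npas4 without TTX replicate 3) to 0.199 (Crh without W15 replicate 1). That of Gadd45b was lost without TTX replicate 1 (adjusted p = 0.0689), 2 (0.0802) or 3 (0.0844), W15 replicate 1 (0.182) or 3 (0.114), or W45 replicate 2 (0.18). Slide as a fixed block ended the calls of Npas4, Ier2, Rgs4 and Gadd45b (adjusted p = 0.125), and normexp also those of Vgf, Nr4a2, Ier2 and Rgs4. Without both W45 replicates 2 and 3, the arrays that stand apart, the calls of Bdnf, Egr1, Npas4, Gadd45b, Nr4a2, Vgf, Crh and Rgs4 were lost, at an adjusted p from 0.0512 to 0.154. The differences of Fosl1, Ch25h and Gadd45g between the times are given under no alternative but the slide block, with which they stayed called, and slide 1 alone (2.52, 3.13 and 1.44).

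A pattern to weigh is the whole set of genes called after washout, since the TTX arrays lie mostly on a slide of their own. With slide as a fixed block, the median log2 fold change of the called genes in their called direction was 2.75 at 15 min (2.67 without the block), 1.90 at 45 min (1.80) and 1.76 between the times (1.76). TTX replicates 2 and 3 are alone on slide 2, so the blocked folds against TTX rest on TTX replicate 1. They show that the folds held against 1 TTX array on a shared slide. That array also helped to choose the genes, so a part played by slides is not settled. Between the times the groups are balanced over slides, so the block could not change the folds. There the median was 1.71 on slide 1 and 1.81 on slide 3. The block did end calls, leaving 0 of 6, 19 of 52 and 22 of 34, while the median SE went from 0.24 to 0.39, from 0.18 to 0.28 and from 0.17 to 0.16 and the median degrees of freedom from 9.2 to 7.5, so for the median gene the calls ended with lower precision or fewer degrees of freedom and not with a smaller fold. The 10 splits of 6 arrays are too few for a share under 0.05, with 6, 52 and 34 genes called by the real split (1 of 10 in each comparison), at most 0, 0 and 1 by the others, and at most 0 by the others that part all pairs of equal replicate number. Return of firing, the difference that the design names, may underlie the set, but the washes and the change of medium that came with it were not separated from it by any group, so that explanation stays untested.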

How the results depend on the processing

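The alternatives with only the 4 arrays of slide 3 and without both W45 replicates 2 and 3 were chosen after the data were seen; all others here were planned. With quantile or median scaling, the mean of all probes, probes above background on all arrays, the replicate block and the random slide block, every gene count stayed within 1.5 times its value (6, 47 and 31 genes higher; 0, 5 and 3 lower). With the replicate block, 39 of the 41 genes higher at 45 min were among the 47, and 3 of the 6 lower were among the 5. Genes higher at 15 min, and genes called at both times, were 2 with normexp correction, 0 with slide as a fixed block and 10 with a trended and robust spread. Genes higher at 45 min were 27 without scaling, 23 with normexp, 30 with only the groups compared and 19 with the slide block. Genes higher between the times were 19 without the filter on dim probes, 15 with normexp, 0 on the 4 arrays of slide 3, 19 with only the groups compared and 17 without both W45 replicates 2 and 3. Genes lower at 45 min were 1 without the filter, 0 with normexp, 1 with only the groups compared, 45 without both W45 arrays (1 of the 5 among them) and 3 with the slide block (0 of the 5 among them). Between the times they were 1 without the filter, 0 with normexp, on slide 3 or with only the groups compared, 5 with the trended spread and 16 without both W45 arrays (0 of the 3 among them). Shifted lists at 15 min were 1 with an estimated correlation and 7 with normexp, and 12 between the times with normexp, against 3 and 5. Of the 3 lists at 15 min, 2 stayed shifted with quantile scaling, no scaling, normexp, the mean of all probes, probes above background on all arrays and fry, and 1 with only the groups compared, the slide block, an estimated correlation or without both W45 arrays. Between the times the replicate numbers are only a shared number by the rule used, since 1 of the 3 correlations was under 0.1 (0.063, 0.183 and 0.151), although each array correlated best with its own number. There the replicate block called 24 genes higher and 3 lower (1 of the 3 among them) and left Ier2 (adjusted p = 0.0781), Nr4a2 (0.101), Crh (0.0781), Gadd45b (0.0597) and Rgs4 (0.0903) not called; besides Gadd45g at 15 min and Rgs4 at 45 min it changed no other call of a list or of a gene with a symbol that was run under the alternatives. Lower counts on slide 3, with only the groups compared and with the slide block go with fewer arrays or fewer residual degrees of freedom. The normexp setting adds an offset of 50 to every signal, which by itself lowers the folds of genes near background. Its share in the lost calls was not tested. Rgs4, well above background, also lost its call at 45 min with normexp (1.02 in the main fit, 1.18 with normexp). For the other alternatives the cause was not tested.

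Leaving out each array in turn gave 2 to 8 genes higher and 0 to 2 lower at 15 min, 27 to 80 higher and 1 to 94 lower at 45 min, and 18 to 63 higher and 0 to 128 lower between the times. It gave 2 to 7 called at both times. The highest counts at 45 min and between the times came without W45 replicate 1, which shares no slide with W45 replicates 2 and 3, the arrays that stand apart on the first principal component (34 and 51.8, others -27.5 to -1.9). The lowest were 2 without TTX replicate 2 or W15 replicate 2 at 15 min, 27 without TTX replicate 2 at 45 min, and 18 without W15 replicate 1 or W45 replicate 2 between the times. No called gene that was run under the alternatives changed direction. Of the lists called at 15 min, the median of the effectors changed sign without scaling (0.16 to -0.05) and that of the late-response genes with normexp and on slide 1 (-0.10 to 0.04 in both). For single genes, 626 of the leave-one-out values kept their side of the threshold or stayed within the spread, 67 lost the call and 9 gained it. Under the other alternatives 933 did so, 98 lost it, 9 gained it and 73 moved by more than the spread. The 73 include called genes on slide 1 alone, where no p value was computed, such as Npas4 between the times (3.34, and 4.42 on slide 1). Slide 1 alone gives values but no counts, and the lists were not tested with the random slide block. Signal over background limits the low end: Npas4 in TTX and Edn1 at 15 min lay below it on all 3 arrays. Normexp took the log2 fold change of Npas4 from 5.71 to 2.55 at 15 min and from 9.05 to 5.44 at 45 min, and that of Edn1 from 3.11 to 1.23 at 45 min and from 3.25 to 0.52 between the times.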

Other observations

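The test of the ania features was chosen after their values were seen. The test of neighbouring unnamed features was written after the names of the called genes were known but before any distance was computed. Of the 47 genes and features higher at 45 min against TTX, 10 have no gene symbol, and 9 of these have coordinates in the files. XM_213050 rose by 2.48 on the log2 scale (adjusted p = 7.98e-05) and RGD1308055 by 1.79 (adjusted p = 0.00241), both named after their values were seen. The array annotation describes XM_213050 as similar to the transcription factor Klf4, which was itself called higher at 45 min. Whether this feature reads the transcript of Klf4 was not tested.

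Some unnamed features, named here after their values were seen, lie beside called genes: AA817984, which was not above background on any TTX array and rose by at least 1.63 over their background limit (1.85 as computed), lies 0.66 kb from the probe of Dusp1 on chromosome 10 and on the opposite strand. CF107866 (1.83) lies 1.18 kb from that of Tent5b on chromosome 5, and TC560958 (1.80) lies 3.05 kb from that of Egr3 on chromosome 15, both on the same strand. These 3 make 33.3% of the 9 features with coordinates, while 15 of the 12303 unnamed features with coordinates lie within 20 kb of a called named gene, and in 10000 random draws of 9 the highest number was 1. Transcription from the same locus as a called named gene, such as an extended 3' end or a transcript of the other strand, may account for these 3 features, while the 6 others are not accounted for by it and whether these probes read the named gene's own transcript was not tested.

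A pattern of another kind concerns sequences filed as ania-5, ania-7 and ania-8, names given to transcripts induced by neuronal activity, which lie within 36.7 kb of one another on chromosome 2. AF030090 (ania-5, 23505728 to 23505787) had a log2 fold change of 3.07 ± 0.41 at 15 min (SE, n = 3 per group, limma adjusted p = 0.125) and rose by 2.74 at 45 min (adjusted p = 0.0451; 2.52 and 2.19 with slide as a fixed block). The call at 45 min was lost with the slide block (adjusted p = 1), the replicate block (0.116), normexp (1.64, 0.87), no filter on dim probes (0.121), only the groups compared (0.244) and without any TTX array, any W15 array or W45 replicate 2 (0.108 to 0.25), while at 15 min the fit of only the groups compared (0.00124) and some others called it. AF050660 (ania-8) had 0.77 and 0.95 (adjusted p = 0.991 and 0.0725), AF050659 (ania-7) had -0.03 and 1.85 (adjusted p = 1 and 0.353), and the Homer1 probe had 0.00 and 0.11. The nearest named probes on either side are those of Tent2, at 162 kb, and Bhmt, at 302 kb, and between these genes the GRCr8 annotation holds 2 protein-coding genes, Homer1 and Jmy, and 6 others. Transcription from the Homer1 locus is therefore a candidate explanation that cannot be told apart from transcription of Jmy or the other genes there, because the Homer1 probe has no coordinates in the files.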
